A study of Mus musculus with 7 samples.

How the data were processed

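The series measured messenger RNA of mouse CD4+ T cells by short-read sequencing. Per the labels, the mice were female C57BL/6 animals with experimental autoimmune encephalomyelitis (EAE), a model of multiple sclerosis. Lymph node cells taken on day 17 were cultured for 18 hours with a myelin peptide at 25 µg/mL, residues 35 to 55 of myelin oligodendrocyte glycoprotein (MOG), and CD4+ T cells were then sorted. The conditional knockout (cKO) group carried floxed Kdm6a and the CD4-Cre transgene, and the wild-type (WT) group consisted of littermates. The 7 libraries were 4 cKO (replicates 2, 3, 7 and 12) and 3 WT (replicates 10, 14 and 19), numbered as in the labels. The labels put 1 library in each column and do not state that each came from a separate animal, so p-values measure the spread between these samples. They give no batch, litter or pairing, and Cre was carried by the cKO group alone, so the effect of Cre cannot be told apart from that of the deletion.

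The deposited values were raw read counts per Ensembl gene, made by the authors and not normalized, as judged from whole numbers with different totals per library. Per the labels' protocols, libraries were prepared with a stranded kit after mRNA enrichment. Per the submitters' processing notes, bcl2fastq 2.17 and the genome build mm10 were used. The aligner, the counting tool, its use of strand and any filter are not given in the sources used here. Genes that overlap on opposite strands, and near-identical paralogs such as the Klra genes, Ly6c1 and Ly6c2, and the Tcrg constant genes, therefore have uncertain shares of reads. The table held 39017 genes, of which 13964 had no count in any library. Symbols and coordinates came from GENCODE gene models on the same build, which matched 37693 identifiers. The remaining 1324 held at most 1.76% of a library's counts. Total counts per library ran from 17910536 (cKO replicate 2) to 28697579 (WT replicate 14). No libraries were duplicates of each other, since the lowest chi-square per gene between any pair was 6.25 times that of sampling noise.

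Counts were filtered with filterByExpr, scaled with TMM factors and tested with the quasi-likelihood test of edgeR 4.0.16 under R 4.3.3, cKO against WT with no covariate. Adjusted p-values are Benjamini-Hochberg values over all 15968 genes tested, with 0.05 as the threshold. Standard errors (SE) of log2 fold changes were derived from the F statistic, and CPM values were computed with edgeR's cpm function and TMM factors. Gene lists fixed before the data were examined (24 function lists and 13 cell type marker lists) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, on log2 CPM with a prior count of 2. The 34 lists with at least 5 tested members were adjusted together. Camera was repeated with an estimated correlation, and fry was run beside it. Of 862 list entries, 848 were matched to the table. Single values were compared by exact two-sided permutation over the 35 splits of 7 libraries into 4 and 3, where the smallest possible p is 0.0286.

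Named genes followed a rule also fixed beforehand: 16 genes always named, then the 12 higher and 12 lower genes with the largest absolute log2 fold change among those past the threshold, with cKO and WT libraries not overlapping and a mean CPM of at least 5. Predicted genes, pseudogenes and antigen receptor segments were excluded from naming. Each function list gives up to 4 examples, those past the threshold with the lowest p, filled up with the most abundant members. Called members of marker lists, and called members beyond 4 in a list, were named after their values were seen. For a gene named in several paragraphs, the libraries whose removal ended its call are given where its values are given. Some genes that this rule names are not reported here.

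The test was checked on simulated counts drawn from these libraries' means, with 200 of 15768 tested genes changed in a cKO against WT comparison and the cholesterol biosynthesis list shifted slightly as a set, which camera called. It called 54% of 50 genes changed by 0.59 on the log2 scale, 68% of 50 changed by 1, 94% of 50 changed by 2 and all 50 changed by 3. Of its 175 calls, 12 (6.86%) were unchanged genes. The 200 changed genes were drawn only from genes above a minimum mean count, and genes were simulated independently with no outlying library. Recovery of low-count genes was therefore not measured. The alternatives were DESeq2 size factors, upper-quartile factors, DESeq2 1.42.0, limma voom with quality weights, no filter, a stricter filter (CPM of at least 1 in 3 libraries and a mean of at least 5), a covariate of B cell, monocyte and dendritic cell markers, a threshold of 0.1, and leaving out each library in turn. Removal of the transcript Gm42418, and leaving out cKO replicates 2 and 7 together, were added after the data were seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.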

Results

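RNA sequencing of CD4+ T cells asked how loss of Kdm6a, an X-linked gene for an enzyme that removes methyl groups from lysine 27 of histone H3, changes gene expression during EAE. The cells came from 4 cKO and 3 WT libraries of antigen-cultured lymph node cells. Total counts were 17910536, 23721927, 22864529 and 20935062 in cKO replicates 2, 3, 7 and 12, and 25360660, 28697579 and 25757761 in WT replicates 10, 14 and 19. Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty had no counts in any library.

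In cKO cells, Klra6, Klra7, Klri2 and Klrd1, which encode receptors best known from natural killer (NK) cells, rose 8.78-fold to 104-fold over WT. The chemokine gene Ccl5 rose from 12.2 ± 4.52 to 140 ± 37.4 CPM (mean ± SD, n = 3 and 4). Eomes, which encodes a T-box regulator of effector lymphocytes, rose 5.71-fold. Dapl1 and Ly6c1, expressed in naive T cells, and the immediate early genes Dusp1, Junb, Ier2 and Fos fell. Of 15968 genes tested with edgeR, 1028 (6.44%) passed the threshold, 446 higher and 582 lower in cKO.

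The floxed gene itself was only modestly lower in whole-gene counts. Kdm6a (ENSMUSG00000037369, chromosome X, 18162575 to 18279936 on mm10) stood at 104, 96.3, 100 and 104 CPM in cKO replicates 2, 3, 7 and 12, and at 120, 125 and 113 CPM in WT replicates 10, 14 and 19. The means were 101 ± 3.67 and 119 ± 6.01 CPM (SD), a log2 fold change of -0.24 ± 0.06 (SE, adjusted p = 0.0414) and a level 15.1% lower. The groups did not overlap (exact permutation p = 0.0286, the smallest that 35 splits allow). Counts over the whole gene cannot show a deletion of some exons whose remaining transcript is still made, and the deleted exons are not given in the sources used here. The call was lost without cKO replicate 3 (adjusted p = 0.0985), 7 (0.0811) or 12 (0.0538), and without WT replicate 10 (0.142), 14 (0.173) or 19 (0.0604), with log2 fold changes between -0.28 and -0.21.

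Neither Kdm6b nor Ezh2 was past the threshold. Kdm6b, which encodes the other H3K27 demethylase, had a log2 fold change of -0.23 ± 0.12 (SE, adjusted p = 0.333), and Ezh2, the H3K27 methyltransferase, had 0.03 ± 0.10 (adjusted p = 0.897). Among 23 tested members of the H3K27 and H3K4 methylation machinery, edgeR called 0, over all genes and adjusted over the list alone. In this list 3 had an unadjusted p under 0.05, and DESeq2 called 1 and limma voom 0. The most abundant, Kmt2d, had 1720 ± 129 CPM in cKO and 1760 ± 131 in WT.

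**Figure D1:**
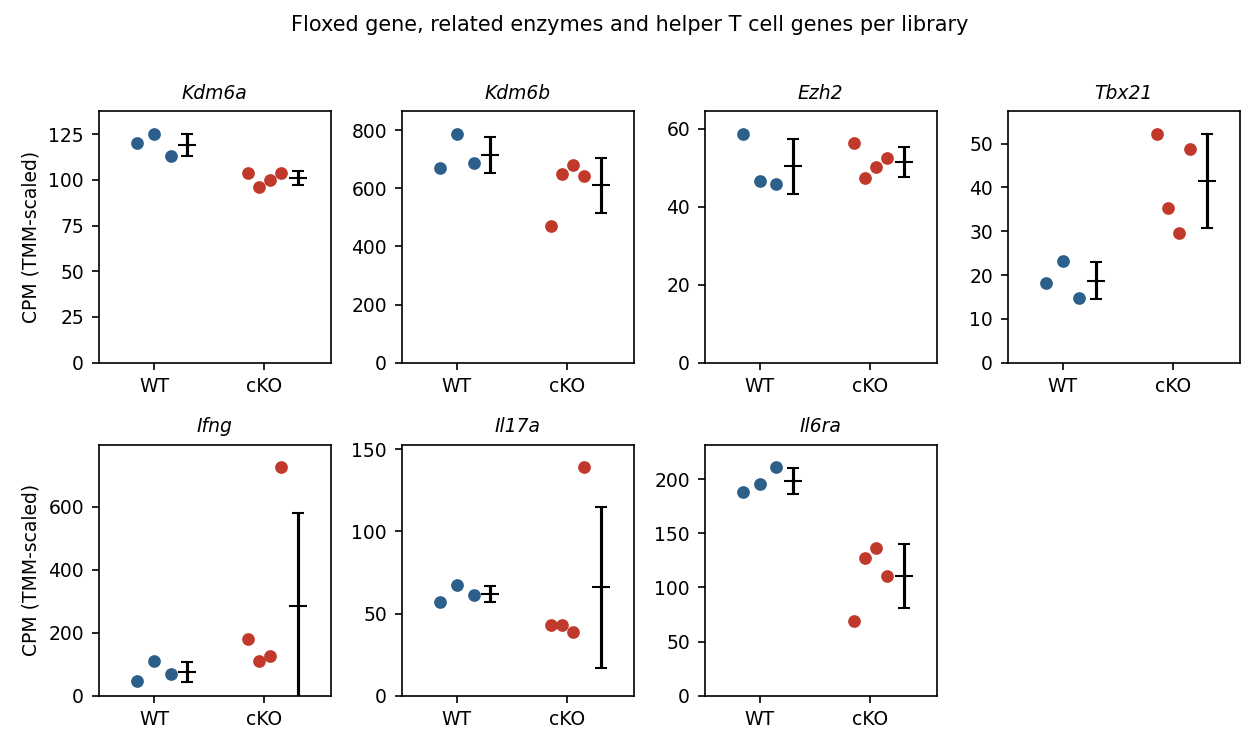
TMM-scaled CPM (y axis, linear, from 0) of 7 genes in each of 3 WT and 4 cKO libraries (points), with the mean and SD beside them (bars, clipped at 0 for Ifng). Kdm6a lies between 96.3 and 104 CPM in cKO and between 113 and 125 in WT, and 1 cKO library has 726 CPM of Ifng and 139 of Il17a.

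The calls were spread over a wide range of effects. At least a 2-fold change was seen in 212 higher and 181 lower genes, and at least 4-fold in 88 higher and 45 lower genes. Of the 1028 calls, 1027 had non-overlapping libraries, as had 21% of all tested genes, where chance gives 5.71%. Leaving out WT replicate 10 lowered the count to 497, WT replicate 14 to 419 and WT replicate 19 to 466. With the level of B cell, monocyte and dendritic cell markers as a covariate it was 660, and limma voom gave 1729 and DESeq2 1608.

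Among genes with a mean CPM of at least 5 and non-overlapping libraries, predicted genes left out, the largest rises after Klra6, Klra7 and Klri2 were in genes of several kinds. Mmp14, which encodes a membrane-bound matrix metalloproteinase, rose 13-fold (log2 3.70 ± 0.22 SE, adjusted p = 3.14e-05). Kifc3, a kinesin gene, rose 12.1-fold and Spry2, an inhibitor of receptor tyrosine kinase signalling, rose 10.6-fold. Crtam, which encodes a cell adhesion receptor of cytotoxic lymphocytes, rose 5.84-fold, and Sprn rose 8.12-fold. Il5, a type 2 cytokine gene, rose 11.6-fold and Nmur1, a neuromedin U receptor gene, 9.76-fold, but their cKO levels of 13.9 ± 11.5 and 13.6 ± 15.1 CPM (SD) varied widely. The Il5 call was lost without cKO replicate 12 (adjusted p = 0.0583) or WT replicate 10 (0.0881), 14 (0.136) or 19 (0.134). The Nmur1 call was lost without the same libraries (adjusted p = 0.0537, 0.134, 0.158 and 0.151). Nmur1 had 35.9 CPM in cKO replicate 2, and its log2 fold change of 3.29 was 2.16 (adjusted p = 0.00536) without that library.

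Under the same conditions, the largest falls were in Dapl1 (log2 -5.04 ± 0.24 SE, adjusted p = 2.09e-05), Lypd6b (-4.13), Igsf23 (-4.11) and Wscd2 (-2.88). Dapl1 had 0.404 ± 0.121 CPM in cKO and 13.6 ± 2.89 in WT (SD). Further falls were in Nacc2 (-2.76), Sorcs2 (-2.75), Eya2 (-2.74), Ly6c1 (-2.58), F2rl1 (-2.20), Lrrc75b (-2.15), Cyp2s1 (-2.07) and Ebi3 (-2.04). F2rl1, which encodes a protease-activated receptor, went from 130 ± 8.86 to 28.3 ± 4.78 CPM. Cyp2s1, a cytochrome P450 gene, went from 79.2 ± 7.61 to 18.8 ± 2.51 CPM. Ebi3 encodes a subunit shared by interleukin 27 and interleukin 35.

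**Figure D2:**
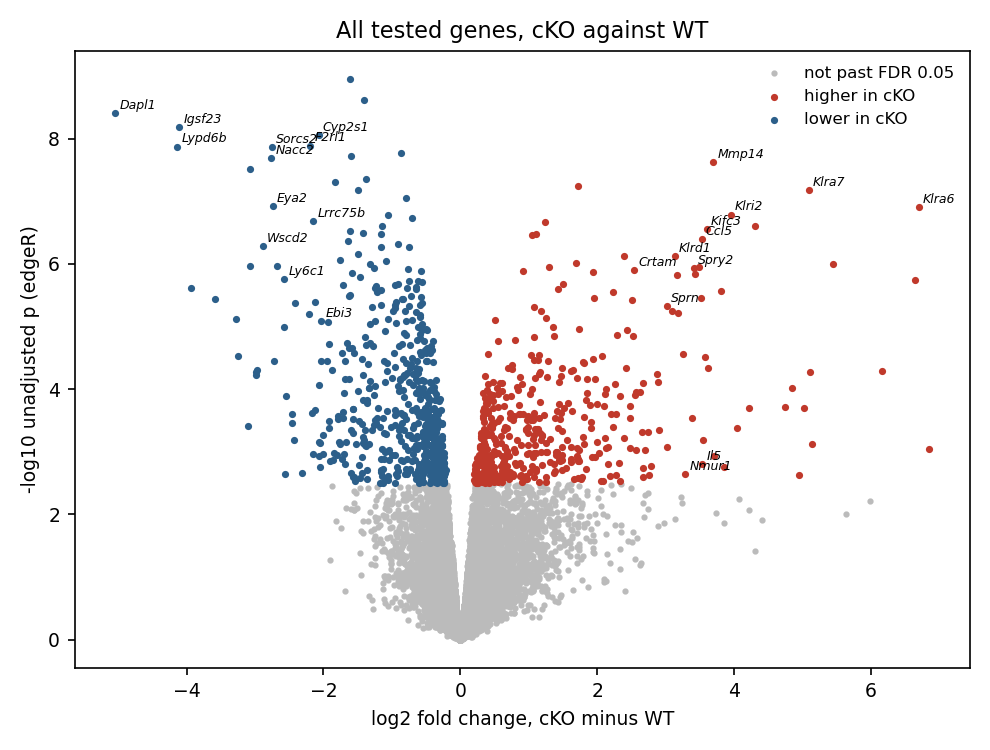
Log2 fold change of cKO over WT (x axis) against -log10 of the unadjusted edgeR p (y axis) for 15968 genes, with the 446 higher genes in red, the 582 lower in blue and the others grey. The 12 largest named changes in each direction are labelled, from Dapl1 at -5.04 to Klra6 at 6.70.

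NK receptor genes rose together. Of 19 tested Klr genes on chromosome 6, a set counted after their values were seen, 16 rose. Klra6 (130013033 to 130026954) had 11 ± 4.26 CPM in cKO against 0.0999 ± 0.0207 in WT, and Klrd1 had 38.8 ± 13.5 against 4.41 ± 0.243. In the NK cell and innate lymphoid marker list, 6 of 9 members rose and 0 fell by edgeR, DESeq2 and limma voom, at an unadjusted p under 0.05 and adjusted over the list alone: Klra7, Klri2, Klre1, Klrc2, Klrb1c and Klra1. The list passed camera (adjusted p = 4.43e-06; adjusted p = 0.557 with an estimated correlation) and fry (adjusted p = 0.00166). Members outside the Klr family were not past the threshold: Ncr1 had 0.887 CPM in cKO and 0.865 in WT, Gzma 1.24 and 1.77, and Prf1 57.7 and 56.0. Shares of reads among the Klra paralogs are uncertain.

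Among helper programs, Th1 genes included the most calls. Of 24 tested Th1 genes, 6 rose and 0 fell by edgeR (11 and 4 adjusted over the list alone, 12 and 4 at an unadjusted p under 0.05), while DESeq2 and limma voom each called 6 higher and 3 lower. The 6 included Ccl5, Eomes (log2 2.51 ± 0.26 SE), Nkg7 (1.64 ± 0.23), Tbx21, which encodes the Th1 regulator T-bet (1.14 ± 0.22), and Cxcr3. Mean log2 CPM of the NK and innate lymphoid markers (2.49 and 0.11) and of the CD8 T cell markers (2.41 and 1.06) was also higher in every cKO than in every WT library. The called members of the NK list were all Klr genes, and Ncr1, Gzma and Prf1 were not past the threshold. Of the CD8 T cell markers only Crtam was called, and Cd8a in cKO replicate 12 (0.28 CPM) was below all WT libraries. Whether such cells contributed to the Th1 calls was not tested. The Th1 list passed camera (adjusted p = 0.0343), but not with an estimated correlation (adjusted p = 0.968 with an estimated correlation), nor without cKO replicate 2 (0.222), WT replicate 10 (0.0642) or WT replicate 19 (0.0819). The Tbx21 call was lost without WT replicate 10 (adjusted p = 0.0694) or 19 (0.0678). That of Cxcr3 was lost without WT replicate 10 (0.096), 14 (0.113) or 19 (0.0937). Ifng had 285 ± 295 CPM in cKO and 75.9 ± 31.5 in WT (log2 1.91 ± 0.66, adjusted p = 0.13), with 726 CPM in cKO replicate 12 and 110 to 179 in the other cKO libraries. Its log2 fold change was 0.86 (adjusted p = 0.124) without cKO replicate 12, and it passed the threshold with the marker covariate (2.31, adjusted p = 0.0421, with 0.0421 to 0.334 over the alternatives).

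Of 24 Th17 genes, 1 rose, Basp1, and 3 fell, among them Sgk1 and Il6ra, the same numbers adjusted over the list alone. Sgk1, a salt-sensitive kinase gene, had a log2 fold change of -0.96 ± 0.18 (SE, adjusted p = 0.0132) and Il6ra, the interleukin 6 receptor gene, -0.84 ± 0.19 (0.0298). The Il6ra call was lost without cKO replicate 12 (adjusted p = 0.0569) or WT replicate 10 (0.0825), 14 (0.106) or 19 (0.118), the Basp1 call without WT replicate 10 (0.0672), 14 (0.104) or 19 (0.111), and the Sgk1 call without WT replicate 14 (0.069). Il17a had a log2 fold change of 0.09 ± 0.41 (adjusted p = 0.934), but of -0.58 (adjusted p = 0.00535, with 0.00535 to 0.986 over the alternatives) without cKO replicate 12, which held 139 CPM against 38.6 to 43.0 in the other cKO libraries. Csf2 had 31.6 ± 20.1 CPM in cKO and 25.4 ± 11.8 in WT (log2 0.31, adjusted p = 0.771), and -0.16 without cKO replicate 12.

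Of 20 Th2 genes, Il4ra and Il5 rose and Ecm1 fell (8 and 4 adjusted over the list alone). Il4ra went from 631 ± 82.8 to 984 ± 103 CPM. Its call was lost without WT replicate 14 (adjusted p = 0.0526), and that of Ecm1 without WT replicate 14 (0.0647) or 19 (0.0761). Gata3 (log2 0.42, adjusted p = 0.173) and Il4 (0.34, 0.683) were not past the threshold. Il4 had -0.09 without cKO replicate 2. Of 22 regulatory T cell genes, Klrg1 and Ikzf2 rose and Ebi3 and Izumo1r fell (4 and 3 adjusted over the list alone). The Ikzf2 call was lost without WT replicate 14 (0.0998) or 19 (0.089). Foxp3 had 180 ± 43.2 CPM in cKO and 153 ± 30.2 in WT (adjusted p = 0.535), and Il10 had 1.94 and 1.01 CPM (log2 0.93, adjusted p = 0.106). Of 20 follicular helper genes, Id3 rose and Izumo1r, Il6ra and Btla fell (3 and 4 adjusted over the list alone), while Bcl6 had 109 ± 15.2 and 108 ± 6.34 CPM (adjusted p = 0.956). The Btla call was lost without cKO replicate 3 (0.0782), 7 (0.0834) or 12 (0.0696) or WT replicate 10 (0.158) or 14 (0.159).

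Genes of naive and central memory T cells were divided. Of 21, Dapl1, Ramp1 (log2 -1.38 ± 0.09 SE), Ly6c1 and Actn1 fell and Bcl2 (0.74 ± 0.12) and Ly6c2 (1.90 ± 0.32) rose (5 and 2 adjusted over the list alone). The Ly6c2 call was lost without WT replicate 14 (adjusted p = 0.0557), and that of Actn1 without cKO replicate 12 (0.0677) or WT replicate 10 (0.0978), 14 (0.106) or 19 (0.133). Shares of reads between the paralogs Ly6c1 and Ly6c2 are uncertain. Ccr7, Lef1, Tcf7, Klf2 and Il7r, also on this list, were not past the threshold, with log2 fold changes between -0.19 and 0.23, and S1pr1, a lymph node egress receptor gene, had -0.07 ± 0.12 (adjusted p = 0.785). Of 27 activation genes, edgeR called Cd6 higher and 0 lower (0 adjusted over the list alone, 5 higher and 6 lower at an unadjusted p under 0.05), DESeq2 2 higher and 4 lower, and limma voom 1 and 3. Il2ra had 735 ± 271 CPM in cKO and 393 ± 62.9 in WT (adjusted p = 0.0709, but 0.0322 without cKO replicate 7 and 0.0239 with no filter, with 0.0239 to 0.229 over the alternatives), and Il2 had 1.41 and 2.25 CPM (log2 -0.67, adjusted p = 0.17). The Cd6 call was lost without cKO replicate 3 (adjusted p = 0.0577) or WT replicate 10 (0.146), 14 (0.166) or 19 (0.0891).

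**Figure D3:**
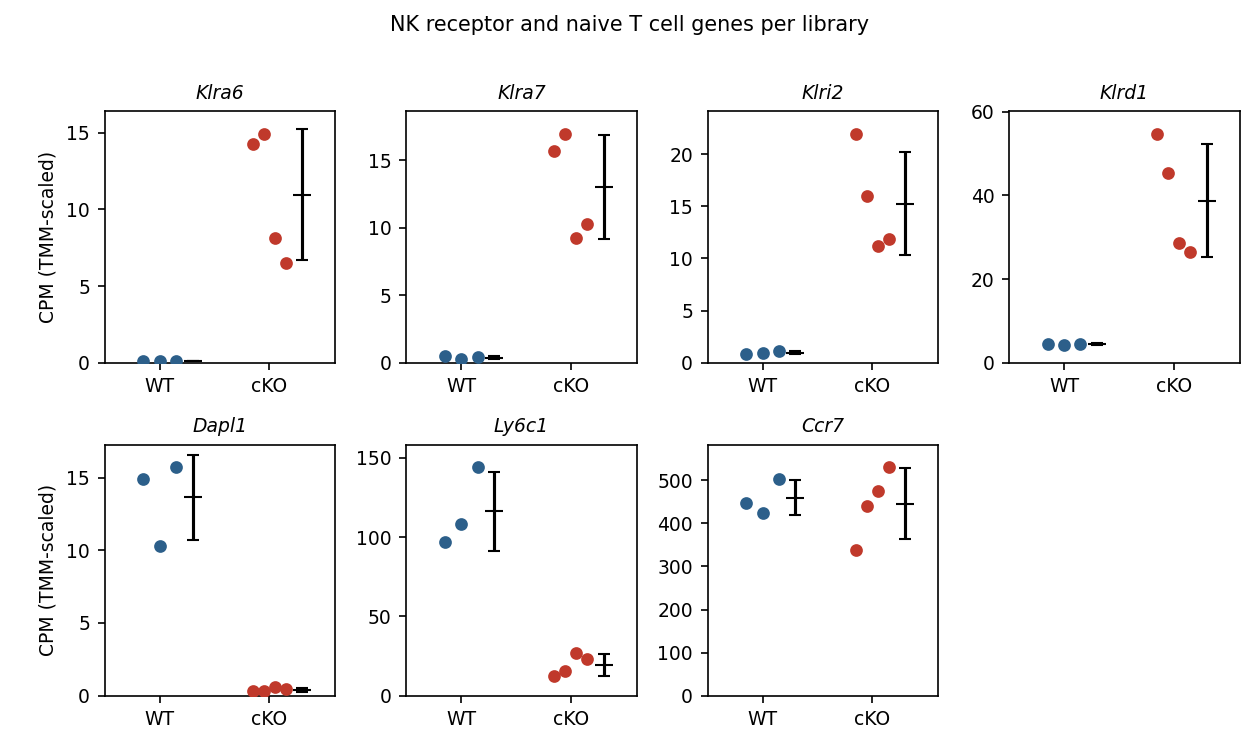
TMM-scaled CPM (y axis, linear, from 0) of 4 Klr genes, Dapl1 and Ly6c1 and the naive T cell gene Ccr7 in each of 3 WT and 4 cKO libraries (points), with the mean and SD beside them. Klra6 averages 11 CPM in cKO and 0.0999 in WT, and Dapl1 0.404 and 13.6.

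Some immediate early genes fell. Of 21 immediate early and heat shock genes, 6 fell and 0 rose by edgeR (8 and 0 adjusted over the list alone or at an unadjusted p under 0.05, 8 and 0 by DESeq2, 7 and 0 by limma voom): Dusp1 from 285 ± 9.28 to 165 ± 5.78 CPM, Junb from 2160 ± 53.7 to 1230 ± 141, Ier2, Fos (log2 -1.12 ± 0.15 SE), Jun and Zfp36. The list passed camera (adjusted p = 0.00309; adjusted p = 0.318 with an estimated correlation) and fry (adjusted p = 0.00147). Egr1 (log2 -0.48, adjusted p = 0.0964) and Nr4a1 (adjusted p = 0.0763), counted among the activation genes and chosen after their values were seen, were not past the threshold. The list was fixed as a marker of sample handling, and no handling times are given in the sources used here.

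Of 39 type I interferon genes, Ifi44 (log2 1.94 ± 0.18 SE), Oasl1 (0.87 ± 0.13) and Oas1a rose and Slfn5 fell (5 and 1 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.07). Of these 39, limma voom called 11 higher and 0 lower, and DESeq2 5 and 2. Of 32 interferon gamma response genes, Cxcl10, Gbp3 and Gbp2 fell and 0 rose by edgeR, also adjusted over the list alone (11 and 2 at an unadjusted p under 0.05, 4 and 0 by DESeq2, 2 and 1 by limma voom). Cxcl10, a chemokine gene, went from 119 ± 30.4 to 36.2 ± 5.73 CPM (log2 -1.72 ± 0.17, adjusted p = 0.00049). The gamma list passed camera as lower (adjusted p = 0.0164; adjusted p = 0.968 with an estimated correlation), but not without cKO replicate 2 (0.164) or WT replicate 19 (0.146). The Oas1a call was lost without WT replicate 10 (adjusted p = 0.0582) or 14 (0.0837), that of Gbp3 without WT replicate 14 (0.0626) or 19 (0.057), and that of Gbp2 without cKO replicate 2 (0.0531), 3 (0.0774) or 12 (0.0762) or WT replicate 14 (0.15) or 19 (0.151). The Slfn5 call (adjusted p = 0.049) was lost without cKO replicate 2 (0.0746), 3 (0.0946) or 12 (0.0636) or WT replicate 10 (0.099), 14 (0.0934) or 19 (0.187).

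Cytokine, receptor and trafficking genes moved in both directions. Of 39 cytokine genes, Ccl5, Tnfsf10, Xcl1, Il6 and Il5 rose and Ebi3 fell (8 and 3 adjusted over the list alone), where Il6 had a log2 fold change of 3.03 from 0.128 CPM in WT. The Il6 call was lost without WT replicate 10 (adjusted p = 0.099) or 14 (0.113), and its log2 fold change was 3.77 without WT replicate 19. The Xcl1 call was lost without WT replicate 10 (adjusted p = 0.0825) or 14 (0.077). Of 36 cytokine receptor genes, Il4ra and Il2rb rose and Ifnar1 (log2 -0.42 ± 0.06 SE), Il17ra and Il6ra fell (6 and 7 adjusted over the list alone). The Il17ra call was lost without WT replicate 14 (adjusted p = 0.05). The Il2rb call was lost without WT replicate 14 (0.0634) or 19 (0.0604). Of 30 chemokine receptor and trafficking genes, 4 rose, among them Ccr10, Ccr1 and Cxcr3, and the integrin genes Itga6 (log2 -1.08 ± 0.10) and Itgb7 (-0.48 ± 0.07) fell (6 and 3 adjusted over the list alone). Of 26 costimulatory and coinhibitory receptor genes, Cd96 (-0.56 ± 0.05), Vsir and Btla fell and 0 rose by edgeR (4 and 2 adjusted over the list alone, 4 and 5 at an unadjusted p under 0.05, 4 and 2 by DESeq2, 4 and 0 by limma voom). The Vsir call was lost without WT replicate 10 (0.052), 14 (0.0794) or 19 (0.0661). Of 28 innate inflammatory genes, Tlr3, Il6 and Tlr2 rose and Tlr1 (-1.15 ± 0.09), Cxcl10 and Tlr6 fell (5 and 3 adjusted over the list alone). Tlr3 lost its call without WT replicate 19 (0.0522), and Tlr2 without cKO replicate 7 (0.0698) or WT replicate 10 (0.114), 14 (0.119) or 19 (0.0733).

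Of 25 apoptosis and survival genes, Bcl2, Bbc3 and Birc2 rose and Fas (log2 -0.70 ± 0.09 SE) and Birc3 fell, the same numbers adjusted over the list alone. The Bbc3 call was lost without cKO replicate 7 (adjusted p = 0.0616) or WT replicate 10 (0.105), 14 (0.0503) or 19 (0.109), that of Birc3 without WT replicate 14 (0.106) or 19 (0.108), and that of Birc2 without cKO replicate 3 (0.0599) or 7 (0.0587) or WT replicate 10 (0.134) or 19 (0.115). Of 25 unfolded protein response genes, Hyou1 rose and Dnajb9 fell (4 and 2 adjusted over the list alone). The Dnajb9 call was lost without cKO replicate 3 (0.0545) or WT replicate 10 (0.0825), 14 (0.101) or 19 (0.0529), and that of Hyou1 without cKO replicate 2 (0.0613), 7 (0.0544) or 12 (0.0604) or any WT replicate (0.165, 0.158 and 0.085 without 10, 14 and 19). Among 10 genes that escape X inactivation, Xist rose by 0.57 ± 0.14 on the log2 scale (SE, adjusted p = 0.0422) and Kdm6a fell, also adjusted over the list alone. The Xist call was lost without cKO replicate 3 (0.093) or WT replicate 10 (0.0978), 14 (0.134) or 19 (0.166).

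Metabolic and growth genes held few calls. Of 40 cell cycle genes, Ccne1 fell (0 adjusted over the list alone), and Mki67 had 231 ± 66.3 and 249 ± 53.6 CPM. Of 19 glycolysis genes, Aldoa fell, also adjusted over the list alone, from 2340 ± 73.3 to 1960 ± 71.5 CPM. The Ccne1 call was lost without any library but cKO replicate 12 (adjusted p from 0.0543 to 0.155), and the Aldoa call without any but cKO replicate 2 (0.0591 to 0.149). By edgeR 0 of 25 cholesterol biosynthesis genes, 0 of 42 oxidative phosphorylation genes and 0 of 52 ribosomal protein genes were called, also adjusted over each list alone. Unadjusted p was under 0.05 for 3, 1 and 8 of them, DESeq2 called 0, 0 and 1, and limma voom 1, 0 and 1. The ribosomal list nevertheless passed camera as lower (adjusted p = 0.0164, median log2 -0.10; adjusted p = 0.968 with an estimated correlation), but not without cKO replicate 2 (0.339) or WT replicate 19 (0.146).

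**Figure D4:**
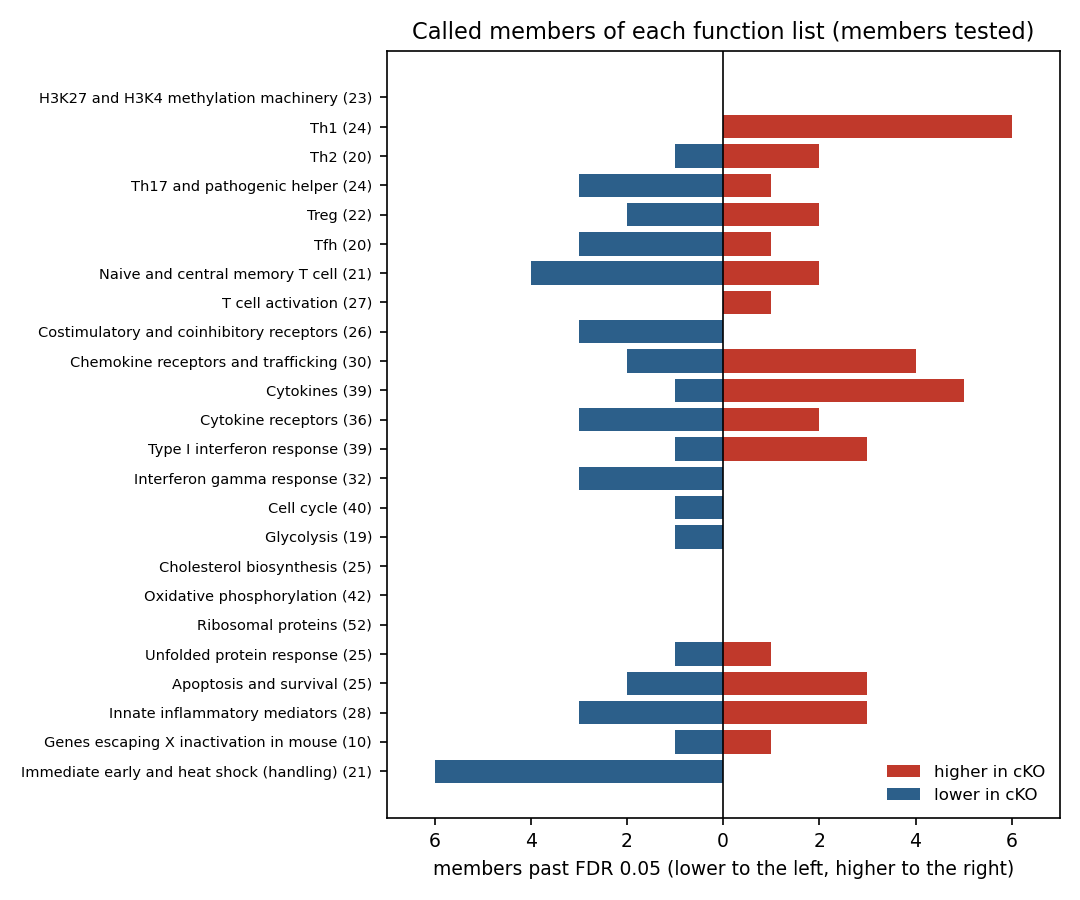
Number of members past the threshold (x axis, lower in blue to the left, higher in red to the right) in each of 24 function lists, with the members tested in brackets. The Th1 list has 6 higher members and the immediate early and heat shock list 6 lower.

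Transcripts listed as markers of other cells were present in both groups, which does not by itself show that those cells were there. Mean log2 CPM was higher in every cKO than in every WT library for 3 of the 13 marker lists, of which the Y-linked list had no tested member. Chance gives 5.71% of lists in either direction, but 21% of all tested genes had non-overlapping libraries. The 3 lists were NK and innate lymphoid (2.49 ± 0.30 and 0.11 ± 0.27, SD, exact permutation p = 0.0286), CD8 T cell (2.41 ± 0.50 and 1.06 ± 0.22, p = 0.0571), and stromal and endothelial markers (1.82 ± 0.45 and 1.01 ± 0.23, p = 0.0571), each with an adjusted p of 0.228. Single members carried much of the last 2 lists. Crtam had 6.96 to 11.9 CPM in cKO and 1.25 to 1.89 in WT, but Cd8a in cKO replicate 12 (0.28 CPM) was below all WT libraries (0.38 to 0.73). Pecam1 had 182 to 221 CPM in every library, and Lum 51.2 in cKO replicate 12 against 6.37 to 7.16 in the other cKO libraries. Mean log2 CPM of 18 B cell markers was 3.74 ± 0.98 in cKO and 2.997 ± 0.55 in WT (SD, exact permutation p = 0.229), with 4.60 in cKO replicate 2, 4.38 in 7 and 2.43 in 12. The B cell, MHC class II, and monocyte and macrophage lists passed camera as higher (adjusted p = 0.0343, 0.0343 and 0.0485), each with adjusted p = 0.968 with an estimated correlation. EdgeR called 0 of their 18, 10 and 17 members, where 1, 6 and 4 had an unadjusted p under 0.05, DESeq2 called 1, 1 and 1 and limma voom 0, 0 and 0. Adjusted over each list alone, 0, 4 and 0 were higher. Without cKO replicate 2, cKO replicate 7 or WT replicate 19 these calls were lost (adjusted p = 0.334, 0.186 and 0.24 for B cell, 0.131, 0.13 and 0.0819 for MHC class II, and 0.361, 0.139 and 0.146 for monocyte and macrophage markers). The last was also lost without WT replicate 14 (0.06). Itgam had 34.6 CPM in cKO replicate 2 and 0.852 to 7.2 in the other cKO libraries.

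Of 16 T cell markers, Thy1 fell, from 562 ± 27.9 to 270 ± 108 CPM, and 0 rose by edgeR (1 and 1 adjusted over the list alone, 2 and 4 at an unadjusted p under 0.05, 2 and 1 by DESeq2 and by limma voom). The Thy1 call was lost without cKO replicate 3 (adjusted p = 0.0543) or 7 (0.0744) or WT replicate 10 (0.113), 14 (0.127) or 19 (0.14). Crtam rose among 3 CD8 T cell markers (3 adjusted over the list alone), where Cd8a had 1.53 CPM in cKO and 0.503 in WT (log2 1.61, adjusted p = 0.171) and Cd8b1 13 and 9.99 (log2 0.38, adjusted p = 0.072). Tcrg-C4 and Tcrg-C2 rose and Sox13 fell among 7 gamma delta T cell markers, also adjusted over the list alone. The Tcrg-C2 call was lost without WT replicate 14 (0.0946) or 19 (0.0852), and that of Sox13 without WT replicate 10 (0.0811) or 14 (0.0658). Sdc1 fell among 11 plasma cell markers and Cacnb3 among 12 dendritic cell markers (1 and 1 adjusted over each list alone). EdgeR called 0 of 9 neutrophil, 0 of 7 stromal and endothelial and 0 of 1 erythroid markers, where 1, 4 and 0 had an unadjusted p under 0.05 and DESeq2 and limma voom called 0. Adjusted over each list alone, 0, 2 and 0 were called. The transcript Gm42418, which overlaps ribosomal RNA sequence, took 9.22% of counts in cKO replicate 2, 3.76% to 4.26% in the other cKO libraries and 2.55% to 2.98% in WT.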

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

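In this part, the tests of an RNA quality gradient, of the share of calls on 1 chromosome, of a segment on chromosome 7 or 15, of the span of the Klr genes without Klrg2 and of a smaller naive share were chosen after the result was seen.

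In 8 of 131 values, 1 of the 4 cKO libraries lay far from the other 3 (by the gap to the nearest library over the whole range, given as a ratio for each), where chance gives about 6.6. cKO replicate 12 stood apart for Il17a (139 against 38.6 to 43 CPM, 0.956), Ifng (726 against 110 to 179, 0.888), Cd6 (562 CPM, 0.863) and the neutrophil marker level (0.871). cKO replicate 2 stood apart for the share of Gm42418 (9.22% of counts, 0.908), Gata3 (227 against 136 to 151 CPM, 0.845) and Kdm6b (470 against 644 to 680 CPM, 0.8294). cKO replicate 7 stood apart for Il2 (1.95 against 1.17 to 1.29 CPM, 0.847). The 3 WT libraries were not tested in this way.

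The first pattern weighed was the number of genes past the threshold, 1028. Of the 35 splits of the libraries, 1, the real one, gave as many, and the highest of the others gave 1 gene. Chance assignment of libraries is thus unlikely but not excluded, since the smallest p that 35 splits allow is 0.0286 (exact permutation). Splits that mix the groups place any group difference within them, and the count cannot tell genotype from another difference between the groups. An RNA quality gradient strongest in cKO replicate 2 was tested on genes called without that library. The measure was its further shift relative to the others' shift from WT, which was 2.5 for Gm42418. The median was -0.002 (bootstrap over genes, -0.051 to 0.05) for 637 lower genes, far below Gm42418, which argues against it there. For 427 higher genes it was 0.245 (0.192 to 0.315), across the bound of 0.25, so for these the gradient stays open. Both medians rest on cKO replicate 2 alone. The bootstrap drew genes and not libraries, so it does not measure the spread between libraries. Choosing genes by a large shift of the other cKO libraries can also lower the ratio. DNA linked to the Cre transgene or floxed locus could give an excess of calls on its chromosome, but a short linked stretch need not. Calls were unevenly spread over 20 chromosomes (smallest adjusted Fisher exact p = 0.0138). There was an excess on chromosomes 7 (8.76% of tested genes called) and 15 (10.09%), but a deficit on 14 (3.57%). On X, which holds the floxed gene, 6.06% were called (adjusted p = 0.856), so no excess was seen there. A test of the whole chromosome cannot exclude a short linked stretch. Near Kdm6a, 3 of 23 genes were called between 20000001 and 25000000 (unadjusted one-sided Fisher exact p = 0.18). The Fisher test treats neighbouring genes as independent. The largest share of the calls on 1 chromosome was 10.3%, on 7, which argues against linked DNA there as the direct source of most calls. None of 422 segments of 5 Mb over all 20 chromosomes passed. The smallest adjusted one-sided Fisher exact p was 0.0671, for a segment on 13 and a segment on 7. For the excess on 7 and 15 and for indirect effects, linked DNA, Cre and loss of Kdm6a cannot be told apart. Per the labels, Cre was in all cKO and no WT libraries.

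The next pattern was the rise of 16 of 19 Klr genes, for which every technical explanation tried stayed open, and for which an effect of Kdm6a loss was not tested. Reads shared between Klra paralogs were not tested either. Such sharing would not raise genes outside the Klra group, where Klrg1 (5.78-fold), Klrk1 (4.91-fold), Klrd1 (8.78-fold) and Klre1 (19.8-fold) were among those called higher. Klrb1b, Klrb1f and Klrg2 were not past the threshold, and 0 Klr genes were called lower. These values argue against read sharing with Klra genes as the cause outside the Klra group. Sharing within other groups called higher, such as Klrc1, Klrc2 and Klrc3 or Klri1 and Klri2, was not tested. Core NK transcripts (Ncr1, Klrb1c, Gzma, Prf1, Tyrobp and Fcgr3) had a median cKO minus WT difference in CPM equal to 22.8% of that of the called Klr genes. This lay between the 10% and 50% bounds set for excluding or favouring NK cells left by the CD4 sort. Klrb1c is itself a Klr gene, and Tyrobp and Fcgr3 are also in the monocyte and macrophage list. Fcgr3 had 7.19 CPM in cKO replicate 2 and 0.76 to 2 in the other cKO libraries, and Tyrobp 5.84 and 1.94 to 2.56. Ncr1, Gzma and Prf1 differed by 0.022, -0.535 and 1.74 CPM. The percent was 2.8% without cKO replicate 2, below the lower bound. It was 26.8%, 13.2% and 14.9% without cKO replicates 3, 7 and 12, and 11.5%, 12.4% and 21% without WT replicates 10, 14 and 19. In cKO replicates 2, 3, 7 and 12 alone it was 27.9%, 3.8%, 14% and -0.7%, on both sides of the lower bound. For CD8 T cells the value was 36.7%, with the same bounds, and 26.5% to 81.7% in single cKO libraries. Cd8b1 differed by 3 CPM and Cd8a by 1.03 CPM. In cKO replicate 12, Cd8a (0.28 CPM) was below all WT libraries (0.38 to 0.73), but Cd8b1 (12.6) was above them (8.74 to 11.11). Passenger DNA around the chromosome 6 Klr genes gave no excess of calls among their neighbours of other families (one-sided Fisher exact p = 0.783, and 0.451 in the span without Klrg2), but the upper bound of the neighbours' share was above that of other genes, so it cannot be told apart from an effect on the Klr genes themselves.

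The last pattern was the fall of Dapl1, Ly6c1 and other genes of naive T cells. A smaller share of naive cells would lower markers as restricted to these cells as Dapl1 (-5.04) about as far. The median log2 fold change over all 21 tested members of the naive and central memory list was -0.063 (quartiles -0.189 and 0.045), and 2 members were below -2. Most members thus did not follow Dapl1. The 7 markers Ccr7, Lef1, Tcf7, Igfbp4, S1pr1, Klf2 and Il7r ran from -0.189 to 0.226, none past the threshold. These values argue against a loss of naive cells deep enough to lower Dapl1 that far only if other CD4+ T cells express the markers less. How far other CD4+ T cells express the markers was not measured, so a smaller naive share stays open. Reads shared between Ly6c1 and Ly6c2 were not tested, and Cre and loss of Kdm6a stay open.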

How the results depend on the processing

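In this part, removal of Gm42418 and leaving out cKO replicates 2 and 7 together were chosen after the data were seen, and the other alternatives were set beforehand. Of 2044 comparisons of a result with its value under an alternative, 1792 kept their direction and side of the threshold (counts: within 1.5 times), 162 kept their direction but lost their call, 3 gained one, 57 reversed and 30 counts moved further. The cause was not tested except where stated. No paired analysis was possible because the labels give no pairs and the groups share no replicate numbers.

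The 1028 calls became 1608 with DESeq2, 1729 with limma voom, 660 with the marker covariate and 1644 at a threshold of 0.1, and 419 to 1065 when each library was left out, where fewer samples were tested (497, 419 and 466 without WT replicates 10, 14 and 19). The 446 higher genes became 761, 802, 238 and 769 under the same alternatives, 257 without cKO replicates 2 and 7, and 146 to 492 when each library was left out (189, 146 and 169 without WT replicates 10, 14 and 19). The 582 lower genes became 927 with limma voom, 875 at the threshold of 0.1 and 273 to 638 when each was left out (308, 273 and 297 without the same WT replicates). Of the 1028, DESeq2 shared 1017 and the marker covariate 595. The 8 lists past the threshold became 13 with DESeq2, 3 with the stricter filter, 2 with the covariate, 0 with an estimated correlation (2 at an unadjusted p under 0.05), 2 with fry, 2 without cKO replicates 2 and 7, and 2 (without cKO replicate 2) to 13 (without cKO replicate 12) when each library was left out, with 4 without WT replicate 19. Marker lists with non-overlapping groups numbered 3, and 3 to 6 when each library was left out, with 6 without cKO replicate 12.

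Kdm6a kept its direction throughout, from -0.275 to -0.207 when each library was left out. Its call was lost with the covariate (-0.255, adjusted p = 0.0907) and without cKO replicates 2 and 7 (-0.259, adjusted p = 0.11), against -0.24 with all libraries and no covariate. The leave-out values are in the report.

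Reversals were in genes not past the threshold and in 2 marker lists. With limma voom, log2 fold changes reversed for Ezh2 (-0.051), Il17a (-0.374), Csf2 (-0.29), S1pr1 (0.033), Icos (-0.138), Bhlhe40 (-0.045) and Rpl4 (0.005). With the marker covariate they did for Ezh2 (-0.033), Bcl6 (-0.06), S1pr1 (0.026), Kmt2d (0.011), Icos (-0.06), Ldha (0.024), Atp5d (0.038) and Rpl4 (0.046), and for the B cell (-0.0385) and monocyte and macrophage (-0.0984) medians, whose markers form the covariate. Without cKO replicates 2 and 7 they did for Ezh2 (-0.019), Il4 (-0.046), Bcl6 (-0.06), S1pr1 (0.007), Kmt2d (0.031), Icos (-0.041), Ldha (0.015), Atp5d (0.023), Rpl4 (0.023) and the monocyte and macrophage median (-0.117). Atp5d went from -0.006 to 0 with upper-quartile factors and 0 with the stricter filter.

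When each library was left out, the ranges of genes that reversed were -0.063 to 0.026 (Atp5d), -0.031 to 0.152 (Ezh2), -0.579 to 0.265 (Il17a), -0.159 to 0.754 (Csf2), -0.132 to 0.024 (S1pr1), -0.112 to 0.206 (Icos), -0.073 to 0.027 (Rpl4), -0.036 to 0.109 (Bcl6), -0.079 to 0.024 (Kmt2d), -0.148 to 0.024 (Ldha), -0.085 to 0.537 (Il4), -0.06 to 0.01 (Laptm5), -0.277 to 0.032 (Mki67) and -0.013 to 0.105 (Calr). Il17a and Csf2 reversed without cKO replicate 12. At this depth and number of libraries, the test on simulated data called 54% of genes changed by 0.59 on the log2 scale, so small changes can be missed. Low-count genes were not among the simulated changes.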

Other observations

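Genes with low p-values outside the naming rule, chosen after their values were seen, included Tbc1d30 (log2 fold change -1.62, adjusted p = 1.77e-05), Ehd3 (-1.41) and Nrn1, which had 101 CPM in cKO and 19.2 in WT.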
